A study of Homo sapiens with 6 samples.

How the data were processed

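RNA was measured in HCT116 cells, an established human colorectal cancer line with an activating CTNNB1 mutation. Per the labels, the cells were held at 1% oxygen for 24 hours with either GIA, a genistein isoflavonoid alkaloid, at 10 µM or the vehicle DMSO at 0.1%, with 3 libraries in each group. Total RNA was extracted with TRIzol and made into strand-specific libraries with a SMARTER mRNA kit, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

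The submitters' processing notes list FastQC 0.10.1, cutadapt, HISAT2 2.2.1, StringTie 2.1.6 and DESeq2 1.22.2 and the builds GRCh38 and hg38, without a role or order for each. The annotation release is not given in the sources used here. The table deposited by the authors holds 30676 genes, with an estimated count and an FPKM (fragments per kilobase of gene, scaled to the size of the library) for each library, per the file headers. The column names give a control or G with a number, which was matched to the numbered control and GIA libraries by their titles. The headers do not say how the counts were made. Over 10002 genes with many counts the ratio of count to FPKM was constant to within 0.200% at the 99th percentile. Low counts piled up at 4 (6798 values, against 4183 at 3 and 2499 at 5) and at 8 (2845 values, against 2157 at 7 and 1515 at 9). The deposited counts were therefore treated as estimated counts derived from coverage, in which 1 fragment may be worth about 4 counts. They were already whole, so rounding them to whole numbers changed nothing. Where overlapping gene models share sequence, the share of reads given to each model is itself an estimate.

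Library totals were 55725249 to 67835059 estimated counts, which count each fragment about 4 times if 1 fragment is worth 4 counts. Each GIA library had a larger total than each DMSO library. FPKM summed to 257020 to 260758 per library, and TMM scaling factors lay between 0.997 and 1.01. The common biological coefficient of variation was 11.0%. No library was a copy of another: the chi-square per degree of freedom of the counts divided by 4 was at least 2.78 in each pair of libraries.

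The comparison was planned with limma on FPKM, to be replaced by a count test if the table also held counts. It did, so the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was used on the estimated counts, two-sided, with TMM scaling and no covariate. Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested (13721 genes), and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors were obtained from the fold change and its F statistic, and 95% intervals from the t distribution with the fitted degrees of freedom. Values are given as FPKM with the SD over 3 libraries, and fold changes are log2, GIA over DMSO. Before the data were examined, 32 gene lists were fixed and 30 had at least 3 tested members; the leukocyte list had 1 tested member and the endothelial list 0. Lists were tested with camera of limma 3.58.1 on log2 CPM (counts scaled to the library total) with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. A list score is the mean over its members of log2 CPM, relative to the 6-library mean. Enrichment of gene ontology terms was planned for called genes and was not run, since no gene was called.

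The genes named were set by a rule: up to 12 genes of the largest and 12 of the smallest fold change among those past the threshold, the 4 members of smallest p in each list that passed, and 18 fixed genes of oxygen sensing, growth and stress. The first part of the rule gave no gene. Some genes that the rule names, and 1 list, are not reported here. Other genes named were chosen after their values were seen. The test was tried on simulated counts drawn for the 13721 genes, with 50 genes changed by each of 4 sizes. It recovered 66% of the genes changed 1.5-fold, 84% of those changed 2-fold and 96% of those changed 4-fold, and fewer (38%) at the smallest size. Of 157 calls, 15 were false, a larger share than the threshold of 0.05 aims for. With no changed gene it called 0 genes, with 662 at an unadjusted p under 0.05. Genes were drawn independently of each other, so the simulated counts hold no correlation between genes and no library that stands apart. The 4 sets of 50 genes were changed in the same run, and the adjustment is stricter where fewer genes change. These shares therefore do not say how often a few changed genes would be recovered. Recovery in the real data may differ.

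Alternatives were limma on log2 FPKM with a pseudocount of 0.1 or 1, or of 0.5 without its mean-variance trend, TPM, no filter, a mean FPKM of at least 5, median-of-ratios size factors, the replicate number as a block, and leaving out each library. Library totals without TMM, counts divided by 4, a robust prior, limma with a pseudocount of 0.5 and its trend, and DESeq2 1.42.0 were added after the data were seen. Overlaps of gene models, correlations and figures were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Coordinates are those of the deposited table, on GRCh38 per the submitters' processing notes.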

Results

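The libraries profiled HCT116 colorectal cancer cells under hypoxia (1% oxygen) after 24 hours with 10 µM GIA or with DMSO, 3 libraries each. The comparison asks which transcripts differ between GIA and the DMSO control when both are under low oxygen. A DMSO content is given for the control libraries only, so whether the GIA libraries had the same DMSO is not known. There was no normoxic group, so the response to hypoxia itself was not measured. DMSO libraries 1 to 3 held 55725249, 56793538 and 63542466 estimated counts, and GIA libraries 1 to 3 held 67833810, 67835059 and 64804849.

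No single transcript passed the test between GIA and DMSO. HIF1A, the oxygen-regulated subunit of the hypoxia-inducible factor, had 59.9 ± 0.431 FPKM with DMSO and 61.4 ± 4.46 with GIA (SD, n = 3 each). MYC had 94.7 ± 1.92 and 96.2 ± 1.42, and CDKN1A, which halts the cell cycle, 28.4 ± 0.810 and 28.8 ± 0.923. Of 13721 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower, and so 0 were at least 2-fold higher or lower. At an unadjusted p under 0.05 there were 630 genes, 363 higher and 267 lower, against 686.05 expected by chance, and the smallest adjusted p was 0.875. DESeq2 also called 0 genes, with 651 at an unadjusted p under 0.05, and limma on FPKM called 0, with 670. The groups did not overlap for 1542 genes (11.2%), where chance gives 10%. Leaving out a library gave a few calls in 4 of 6 cases: 1 higher and 1 lower without DMSO library 2, 2 higher without DMSO library 3, 1 higher without GIA library 1, and 2 higher and 3 lower without GIA library 3. The number at an unadjusted p under 0.05 was 1407 without GIA library 1 and 406 without DMSO library 2, and 479 to 578 without any other single library.

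For most tested genes the intervals bound the size of a change between these samples. The 95% interval lay within 2-fold either way for 12749 genes (92.9%) and within 1.5-fold for 11386 (83.0%). Among the 7006 genes with a mean FPKM of at least 5, these shares were 99.5% and 98.5%. The interval of CA9 reached 4.16-fold. These are intervals of single genes and are not adjusted for their number. If the libraries of a group are technical, the intervals leave out the spread between cultures.

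Of the 18 genes fixed in advance, 0 passed the test, each with an adjusted p of at least 0.875 by edgeR. VEGFA, the angiogenic growth factor (chromosome 6, 43770184 to 43786487), had at most 15.5 FPKM in the DMSO libraries and 16.1, 17.5 and 16.3 in the GIA libraries, a log2 fold change of 0.15 (SE 0.05, 95% interval 0.05 to 0.26). CA9, the hypoxia-induced carbonic anhydrase (chromosome 9, 35673918 to 35681159), had 18.1, 4.17 and 9.23 FPKM in the DMSO libraries and 9.50, 32.8 and 15.3 in the GIA libraries. Its log2 fold change was 0.87 (SE 0.53, interval -0.32 to 2.06), with 0.24 without GIA library 2, 0.49 without DMSO library 2 and 1.51 without DMSO library 1. The mitophagy receptor BNIP3 had 8.84 ± 1.70 and 10.8 ± 2.23 FPKM, a log2 fold change of 0.28 (SE 0.16). SLC2A1, a glucose transporter, had 0.10 (SE 0.06), and LDHA, which makes lactate, 0.04 (SE 0.03). For HIF1A the log2 fold change was 0.03 (SE 0.05, interval up to 1.10-fold), for ARNT 0.06 (SE 0.04) and for VHL 0.09 (SE 0.04). PDK1 had -0.02 (SE 0.07). The proliferation marker MKI67 had 0.02 (SE 0.03) and CCND1, which encodes cyclin D1, -0.10 (SE 0.11). Stress and metabolic genes lay in the same range: HMOX1 had 0.16 (SE 0.11), DDIT3 -0.13 (SE 0.08), HMGCS1 -0.10 (SE 0.05) and CYP1A1 -0.02 (SE 0.11). Several of these values rested on single libraries. With GIA library 2 left out, BNIP3 had 0.12, SLC2A1 0.05, LDHA 0.0072, HMGCS1 -0.05 and HMOX1 0.25, and the sign changed for CCND1 (0.02), HIF1A (-0.02) and CYP1A1 (0.08). ARNT had 0.04 there and also without DMSO library 3. MKI67 had 0.05 without GIA library 2, 0.0065 without GIA library 1 and 0.0099 without DMSO library 3. Without DMSO library 2, BNIP3 had 0.14, SLC2A1 0.05, LDHA 0.03, CCND1 -0.05, HMOX1 0.10 and DDIT3 -0.21, and DDIT3 had -0.08 without DMSO library 3. Without GIA library 1, CCND1 had -0.22, CYP1A1 -0.16, HMOX1 0.09, HIF1A 0.07 and LDHA 0.07. HIF1A had 0.05 and CYP1A1 -0.0060 without GIA library 3. PDK1 changed sign without DMSO library 1 and without GIA library 3, with 0.02 in both, and had -0.07 without DMSO library 3 or GIA library 2 and -0.0020 without DMSO library 2. Of the 59 genes that the naming rule gave, 36 moved by over 1.5 times or changed sign without GIA library 2, against 4 to 12 without any other single library. Most of the 59 were named from lists that passed with all libraries, and most of those lists did not pass without GIA library 2. Part of this shift may therefore come from the choice of genes. For a fold change near 0, a small shift is enough to move it by over 1.5 times.

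**Figure D1:**
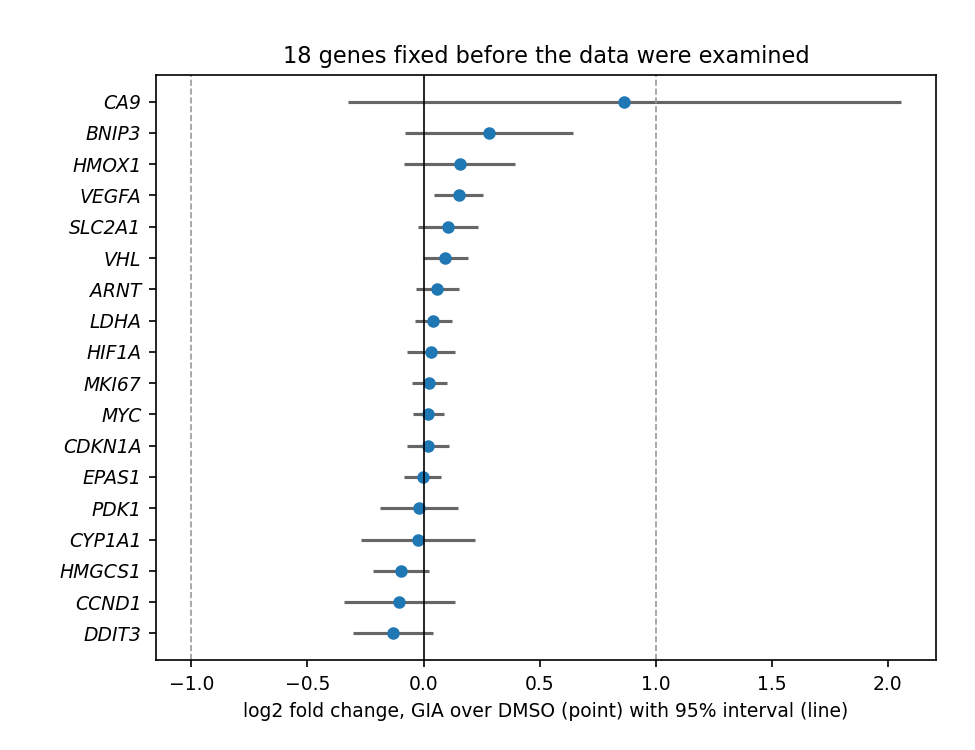
Log2 fold change of GIA over DMSO for 18 genes, with points for the edgeR estimate from 3 libraries per group and lines for the 95% interval; dashed lines mark 2-fold. CA9 has the widest interval, -0.32 to 2.06, and VEGFA lies at 0.15.

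**Figure D2:**
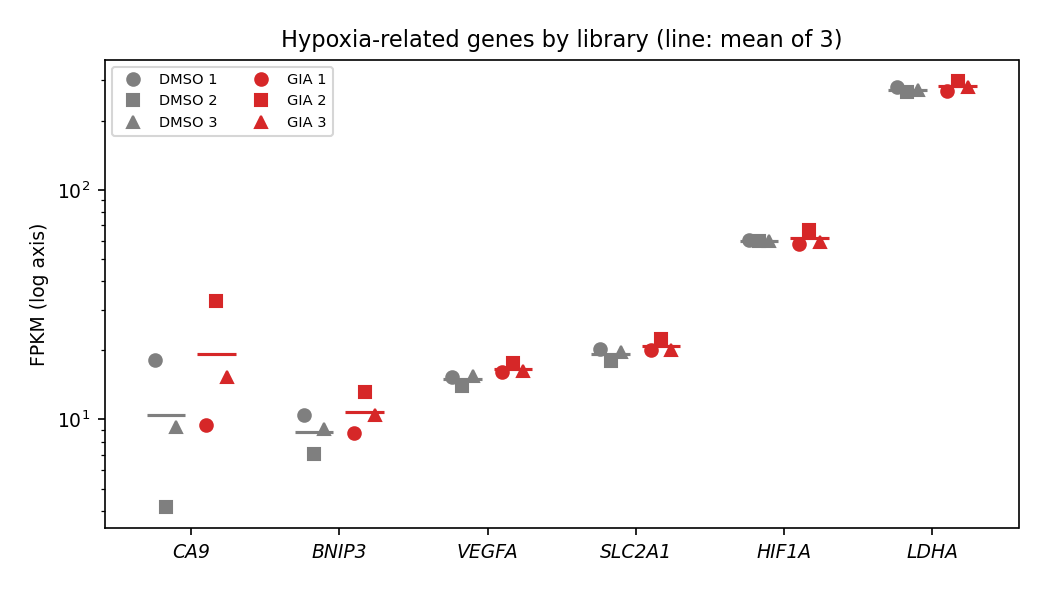
FPKM on a log axis of 6 genes in each library, with grey symbols for DMSO, red for GIA, shapes for the library number and lines for the mean of 3. CA9 ranges from 4.17 to 18.1 with DMSO and from 9.50 to 32.8 with GIA.

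Genes induced by hypoxia and genes of glycolysis lay slightly higher with GIA as lists, by camera with a preset correlation. The estimated correlations of these 2 lists were 0.33 and 0.43. By exact permutation of the list scores p was 0.5 and 0.2, where 0.1 is the smallest possible. The 41 tested hypoxia-inducible genes outside glycolysis had a median log2 fold change of 0.10, with 35 positive and 6 negative (adjusted p = 1.8e-05; adjusted p = 0.639 with an estimated correlation). None rose or fell and 41 did not pass. Examples are the glycogen branching enzyme GBE1 at 0.10 (SE 0.04), WSB1 at 0.18 (SE 0.09) and PPFIA4 at 0.72 (SE 0.34). The 22 glycolysis genes had a median of 0.05, with 20 positive (adjusted p = 0.00115; adjusted p = 0.670 with an estimated correlation), and 22 did not pass. GPI had 0.07 (SE 0.03), GAPDH 0.06 (SE 0.04) and the glucose transporter SLC2A3 0.81 (SE 0.32) at under 1 FPKM in both group means. Leaving out GIA library 2 gave 0.06 for WSB1, 0.32 for PPFIA4, 0.33 for SLC2A3 and 0.02 for GAPDH. PPFIA4 had 1.09 without DMSO library 1 and 0.46 without DMSO library 2, GPI 0.05 without DMSO library 2 and WSB1 0.28 without GIA library 1. On the log2 (FPKM + 0.5) scale of limma, which understates changes of low genes, PPFIA4 had 0.41 and SLC2A3 0.39, and 0.29 and 0.27 with a pseudocount of 1. The adjusted p without GIA library 2 became 0.0943 for the hypoxia list, with a median of 0.03, and 0.170 for glycolysis, with a median of 0.02. Without DMSO library 2 the hypoxia median was 0.07, and glycolysis had an adjusted p of 0.126 and a median of 0.02. Without DMSO library 1 the glycolysis median was 0.09.

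Genes of ribosome production, nuclear-encoded mitochondrial respiration and protein folding lay slightly lower with GIA as lists, by camera with a preset correlation of 0.01. Their estimated correlations were 0.60, 0.07 and 0.58. Exact permutation of the list scores gave p = 0.3, 0.1 and 0.5, where 0.1 is the smallest possible. The heat shock score was lowest in GIA library 2 (-0.17) and highest in GIA library 1 (0.05). All 31 ribosome biogenesis and MYC target genes had a negative fold change, with a median of -0.07 (adjusted p = 4.22e-09; adjusted p = 0.639 with an estimated correlation). NPM1, a nucleolar chaperone, had -0.07 (SE 0.03), POLR1A, the large subunit of RNA polymerase I, -0.14 (SE 0.06), LYAR -0.18 (SE 0.07) and RRP9 -0.20 (SE 0.08). Of 44 nuclear genes of oxidative phosphorylation 38 were negative, with a median of -0.04 (adjusted p = 0.000456; adjusted p = 0.639 with an estimated correlation). ATP5MC1 had -0.10 (SE 0.04), NDUFA9 -0.08 (SE 0.04), COX8A -0.07 (SE 0.04) and ATP5F1B -0.05 (SE 0.03). The 18 heat shock genes had a median of -0.06 (adjusted p = 0.000456; adjusted p = 0.670 with an estimated correlation), with HSP90AA1 at -0.09 (SE 0.05), FKBP4 at -0.08 (SE 0.04), HSPD1 at -0.06 (SE 0.03) and CHORDC1 at -0.11 (SE 0.07). No member of these lists rose or fell: 31, 44 and 18 did not pass. Without GIA library 2 the ribosome list had an adjusted p of 0.00251 and a median of -0.03, and the heat shock list an adjusted p of 0.908 and a median of -0.01. Without GIA library 1 these medians were -0.10 and -0.10. Leaving out GIA library 2 gave -0.08 for POLR1A, -0.10 for RRP9, -0.04 for FKBP4, -0.03 for HSPD1, and -0.02 for HSP90AA1 and CHORDC1, and HSP90AA1 had -0.14 without GIA library 1.

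Cholesterol, antioxidant and amino acid stress lists also lay lower by camera with the preset correlation. By exact permutation of the list scores p was 0.2, 0.7 and 0.2. The 25 cholesterol genes had a median of -0.06 (adjusted p = 0.000456; adjusted p = 0.639 with an estimated correlation), with CYP51A1 at -0.13 (SE 0.06), FDPS at -0.06 (SE 0.03) and HSD17B7 at -0.14 (SE 0.07). The 29 NRF2 genes had a median of -0.06 (adjusted p = 0.00443; adjusted p = 0.833 with an estimated correlation). UGDH had -0.17 (SE 0.05), thioredoxin (TXN) -0.09 (SE 0.04) and ferritin light chain (FTL) -0.15 (SE 0.08). The 31 ATF4 genes had a median of -0.03 (adjusted p = 0.00979; adjusted p = 0.722 with an estimated correlation), with the glutathione-degrading enzyme CHAC1 at -0.29 (SE 0.10), NUPR1 at -0.08 (SE 0.04) and MTHFD2 at -0.07 (SE 0.04). None of the 25, 29 and 31 members rose or fell. Leaving out GIA library 2 gave -0.06 for CYP51A1, -0.05 for TXN, -0.05 for FTL and -0.04 for MTHFD2. FTL had -0.25 without GIA library 1 and HSD17B7 -0.08 without DMSO library 3. For the lists, the adjusted p values without GIA library 2 were 0.170, 0.614 and 0.908 and the medians -0.02, 0.02 and 0.0013, so that the NRF2 and ATF4 medians changed sign. Without GIA library 1 the medians were -0.10, -0.13 and -0.06. Without DMSO library 2 the NRF2 list had an adjusted p of 0.0767 with a median of -0.04, and the ATF4 list 0.0621 with a median of -0.02; without DMSO library 3 the ATF4 list had 0.0513 with a median of -0.03. With a mean FPKM of at least 5, the NRF2 list had an adjusted p of 0.05, at the threshold and not under it, with a median of -0.05, and the ATF4 list 0.113 with a median of -0.02.

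Cell cycle lists lay apart by small amounts, by camera with the preset correlation. By exact permutation of the list scores p was 0.3 for G1/S, 0.1 for G2/M and 0.6 for histones, where 0.1 is the smallest possible. The 34 G1/S and DNA replication genes had a median of -0.03 (adjusted p = 0.00768; adjusted p = 0.639 with an estimated correlation), with MCM4 at -0.08 (SE 0.03), MCM5 at -0.06 (SE 0.04), TIPIN at -0.12 (SE 0.07) and E2F2 at 0.09 (SE 0.05). The 34 G2/M genes had a median of 0.02 (adjusted p = 0.0187; adjusted p = 0.639 with an estimated correlation), with the kinesin KIF20A at 0.09 (SE 0.04), TOP2A at 0.07 (SE 0.03), CENPE at 0.12 (SE 0.06) and CDC25C at 0.13 (SE 0.08). The 28 replication-dependent histone genes had a median of 0.09 (adjusted p = 0.0433; adjusted p = 0.850 with an estimated correlation), with H2BC17 at 0.57 (SE 0.20), H2BC7 at 0.71 (SE 0.26), H3C10 at 0.43 (SE 0.18) and H2BC9 at 0.47 (SE 0.20). Histone genes resemble each other, so the share of reads given to each may be uncertain. H2BC7 was under 1 FPKM in both group means (0.55 and 0.91). The histone score was 0.34 in GIA library 2 and between -0.21 and 0.04 in each other library. None of the 34, 34 and 28 members rose or fell. Leaving out GIA library 2 gave -0.05 for TIPIN, 0.06 for E2F2, 0.04 for TOP2A, 0.07 for CENPE and 0.27 for H2BC9. H2BC7 had 0.41 by limma with a pseudocount of 0.5. For the lists, the adjusted p values without GIA library 2 were 0.423, 0.170 and 0.693, with medians of -0.0036, 0.02 and -0.03. The G2/M list had 0.0599 without DMSO library 2 and 0.0530 without DMSO library 3, with a median of 0.02 in both, as with all libraries. The histone list had 0.310 and a median of 0.06 without DMSO library 3, and a median of 0.15 without DMSO library 2 or GIA library 1. The G1/S median was -0.04 without GIA library 1 or GIA library 3. With a mean FPKM of at least 5 the G1/S list had an adjusted p of 0.0749 and a median of -0.02, and the histone list 0.128 and 0.06. The histone list also did not pass with no filter (0.0973, median 0.22) or with library totals in place of TMM (0.0552, median 0.10).

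In all, 11 of 30 lists passed with the preset correlation, 4 higher and 7 lower, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05), and 0 passed by fry (smallest adjusted p 0.781). Adjusted over the list alone, 0 members of any list rose or fell. Without GIA library 2, 5 lists passed, of which 2 were among the 11: ribosome biogenesis and nuclear oxidative phosphorylation. The other lists passing there were the mitochondrially encoded mRNAs (adjusted p 2.7e-07), cytosolic ribosomal proteins (1.46e-06) and mesenchymal and matrix genes (0.0232). Without DMSO library 2, 7 lists passed.

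**Figure D3:**
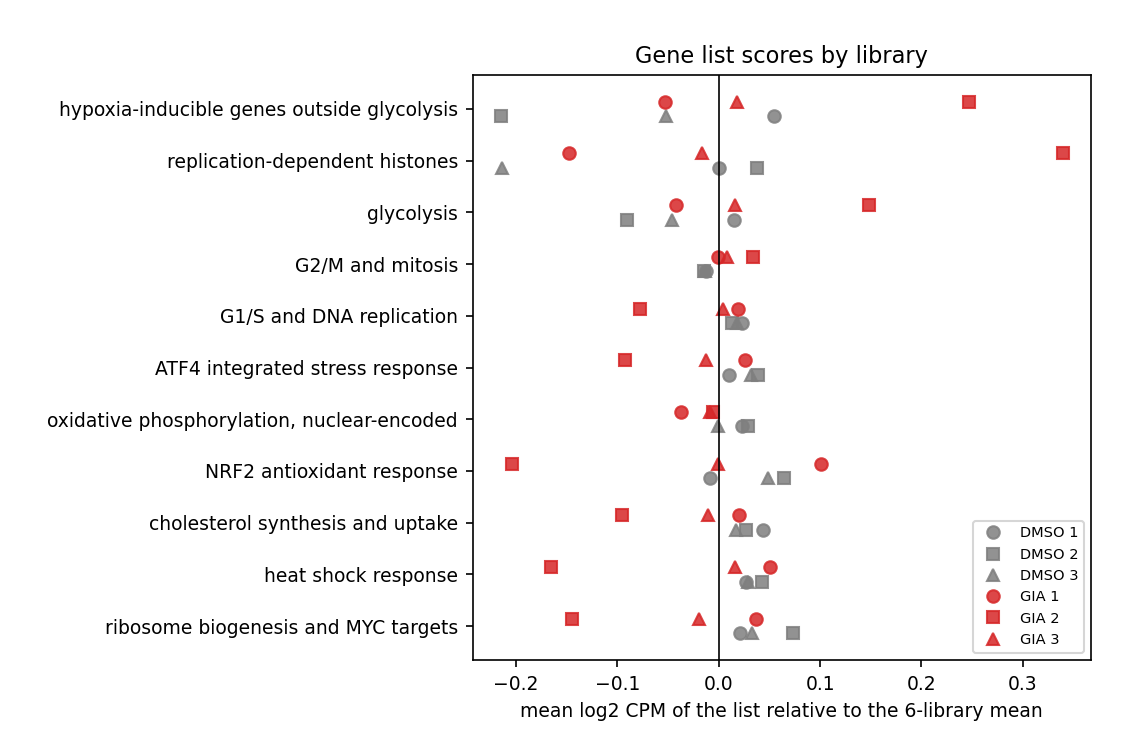
Score of each of the 11 lists in each library, as the mean log2 CPM of its members relative to the 6-library mean, with grey symbols for DMSO, red for GIA and shapes for the library number. GIA library 2 lies at 0.25 for the hypoxia list and -0.20 for the NRF2 list, while GIA library 1 lies at -0.05 and 0.10.

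The remaining 19 lists did not pass, with no member past the test. With all 6 libraries the adjusted p was 0.0683 for 38 cytosolic ribosomal proteins (median -0.01), 0.131 for 13 mitochondrially encoded mRNAs (0.02), 0.127 for 23 mesenchymal and matrix genes (0.02), 0.131 for 22 interferon-stimulated genes (0.04), 0.131 for 10 oestrogen response genes (0.07) and 0.127 for 5 intestinal differentiation genes (0.33). Markers of fibroblasts, another cell type, had 5 tested members, a median of 0.14 and an adjusted p of 0.174. It was 0.253 for 22 pro-apoptotic genes (-0.02) and 0.760 for 9 anti-apoptotic genes (0.01). It was 0.760 for 26 MAPK output genes (-0.02) and 0.792 for 15 epithelial genes (0.01). The unfolded protein response (21 genes), aryl hydrocarbon receptor targets (7), fatty acid synthesis (14), NF-kB and inflammatory genes (19) and metallothioneins (3) each had 0.857. The 9 Wnt targets had 0.938 and the 33 lysosome and autophagy genes 0.991. Without GIA library 1, the interferon list (3.56e-05), the MAPK list (0.0143), the intestinal list (0.0143) and the fibroblast list (0.0110) passed, and without DMSO library 1 the mitochondrially encoded mRNAs did (0.0102). With no filter on low values the cytosolic ribosomal proteins passed (0.0115). The intestinal median was 0.02 without GIA library 2, 0.21 without DMSO library 2 and 0.54 without GIA library 1. The interferon median was -0.06 without GIA library 2, 0.15 without GIA library 1 and 0.02 without DMSO library 3, and the fibroblast median 0.0062 without GIA library 2. The median of the mitochondrially encoded mRNAs was 0.06 without GIA library 2, -0.0034 without GIA library 1 and -0.02 without GIA library 3. That of the mesenchymal and matrix genes was 0.05 without GIA library 2 and 0.0025 without GIA library 1, and that of the cytosolic ribosomal proteins -0.03 and 0.0042. The MAPK median was 0.02 without GIA library 2 and -0.15 without GIA library 1. Each of the 19 medians moved by over 1.5 times or changed sign without at least 1 library, and 13 changed sign.

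Libraries of the same group were about as close to each other as libraries of different groups. Correlations of log2 values ran from 0.987 to 0.990 within groups and from 0.986 to 0.990 between them, and the mean distance between groups was 1.00 times that within. By a chi-square of its counts GIA library 2 stood apart: the chi-square per degree of freedom was 6.03 to 9.78 in its 5 pairs and 2.78 to 4.33 in the 10 pairs without it. By principal components of the log2 values it was not the only one. DMSO library 2 lay at -29.2 and GIA library 2 at 20.2 on component 1 (24.5% of the variance), and on component 2 (23.2%) DMSO library 3 lay at -23.8, GIA library 2 at 19.5 and DMSO library 2 at 11.8. DMSO library 2 also had the lowest hypoxia score, -0.22, and GIA library 2 the highest, 0.25.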

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

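Library totals without TMM, counts divided by 4, a robust prior, limma with a pseudocount of 0.5 and DESeq2 were chosen after the data were seen, as were the counts of splits. Of 19 alternatives to the test, those without an omitted library or a block gave 0 genes higher and 0 lower, with 307 to 1081 at an unadjusted p under 0.05. DESeq2 left 13 adjusted p values undefined, and its smallest was 0.0937. The replicate block gave 1 gene higher (AL591806) and 2 lower (C19orf71 and PDCD6-AHRR), each at least 2-fold, and kept the 11 lists. AL591806 had 0 FPKM in each DMSO library and 3.59, 4.42 and 0 in GIA libraries 1 to 3. C19orf71 had 9.08, 0 and 9.85 FPKM in DMSO libraries 1 to 3 and 0 in each GIA library. PDCD6-AHRR had 10.9 FPKM in DMSO library 3 and 0 in each other library. These calls rest on values of 0, and that of PDCD6-AHRR on 1 library. The cause was not tested. Deviations of libraries of the same number correlated by 0.0519, 0.0334 and 0.0966, each under the 0.1 asked for in every pair, so the numbers were not taken to pair the libraries; as a hint the other way, 5 of 6 libraries correlated best with their own number. Leaving out 1 library gave 0 to 2 genes higher, 0 to 3 lower, 0 to 2 at least 2-fold higher, 0 to 3 at least 2-fold lower and 5 to 15 lists, with fewer samples in each fit. With a mean FPKM of at least 5, 7 lists passed among fewer genes tested; with an estimated correlation 0 passed, and by fry 0. No named gene passed in 1112 combinations of gene and alternative, and 8 of these had another sign. Lists had another direction in 31 of 538. The largest shift of the median log2 fold change was 0.007. The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 0 genes in each direction and at each size, and the highest other 2. All 10 splits gave at least as many genes, which was fixed in advance since none can give fewer than 0, so this tests nothing. At least the real 11 lists passed in 4 of the 10 splits, the highest other 15. The split of DMSO 1, GIA 2 and GIA 3 against the rest had 1147 genes at an unadjusted p under 0.05, against 630 in the real split. Ontology enrichment was not run under any alternative of the test, including those that called a few genes. Fewer counts give less precision, and 83.0% of all tested genes, against 98.5% of those at a mean FPKM of at least 5, had an interval within 1.5-fold; how much of this difference comes from depth was not tested.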

Other observations

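The overlap of the groups' hypoxia scores, the comparison of GIA libraries 1 and 2, the interval of the correlation of score and depth, and the correlations of scores with each other were tests chosen after the result was seen. Single genes varied between libraries of the same group. Among genes with a mean FPKM of at least 5 and no overlapping model, the pseudogene RPS26P6, a copy whose reads are uncertain, ranged from 5.43 to 27.8 FPKM. IGFBP3, a binding protein of insulin-like growth factors, had 16.1, 8.95 and 13.1 FPKM in the DMSO libraries and 12.5, 22.6 and 15.6 in the GIA libraries. ALPI, the intestinal alkaline phosphatase, had 7.84 to 11.7 with DMSO and 7.98 to 20.8 with GIA, with the highest value in library 2. The mucin MUC13 had 43.3 to 47.4 FPKM with DMSO and 38.9, 64.5 and 48.8 with GIA. Interferon-stimulated ISG15 had 115 to 117 with DMSO and 92.6, 141.0 and 116 with GIA. The matrix proteoglycan LUM, on the fibroblast list, had 157 to 197 FPKM over the 6 libraries. These genes were chosen after their values were seen, and none passed the test between groups.

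Over the 6 libraries the hypoxia score was compared with the scores of the other 10 lists that passed with the preset correlation. These lists were chosen by a shift in the same libraries, and most did not pass without GIA library 2. They may therefore vary together through that choice, for which the permutation p values do not allow. Pearson r was also taken without the 2 libraries farthest from the median hypoxia score, DMSO library 2 and GIA library 2. This narrows the range of that score and leaves few libraries. A change of r there cannot tell whether a relation rests on those 2 libraries. Glycolysis had a Pearson r of 0.976 (exact permutation p = 0.0111, adjusted p = 0.0556) and a Spearman rho of 0.886 (exact p = 0.0333, adjusted p = 0.0667), with r = 0.953 without the 2 farthest libraries. The ATF4 list had r = -0.91 (exact p = 0.0111, adjusted p = 0.0556) and rho = -0.89 (exact p = 0.0333, adjusted p = 0.0667), with r = -0.71 without them. Ribosome biogenesis had r = -0.93 (exact p = 0.0194, adjusted p = 0.0648) and rho = -0.94 (exact p = 0.0167, adjusted p = 0.0667), with r = -0.55 without them. The NRF2 list had r = -0.88 (exact p = 0.0417, adjusted p = 0.104) and rho = -0.94 (exact p = 0.0167, adjusted p = 0.0667), with r = -0.89 without them. Heat shock went from r = -0.84 (exact p = 0.0528, adjusted p = 0.106) to -0.61 without them. The histone list went from 0.644 (exact p = 0.172, adjusted p = 0.215) to 0.940. For the other 4 lists r lay near 0 or had another sign without them. G2/M went from r = 0.812 (exact p = 0.0722, adjusted p = 0.120) to 0.0172 and G1/S from -0.77 (exact p = 0.219, adjusted p = 0.244) to -0.09. Cholesterol went from -0.76 (exact p = 0.164, adjusted p = 0.215) to 0.227, and nuclear oxidative phosphorylation from -0.25 (exact p = 0.672, adjusted p = 0.672) to 0.732. Their Spearman rho values were -0.89 for heat shock (exact p = 0.0333, adjusted p = 0.0667), 0.371 for histones (exact p = 0.497, adjusted p = 0.622), 0.714 for G2/M (exact p = 0.136, adjusted p = 0.227), -0.26 for G1/S (exact p = 0.658, adjusted p = 0.731), -0.43 for cholesterol (exact p = 0.419, adjusted p = 0.599) and -0.14 for oxidative phosphorylation (exact p = 0.803, adjusted p = 0.803). None of the 10 relations passed after adjustment, and with 3 libraries a group could not be taken alone.

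The hypoxia list ranged widely between libraries of the same group. Its scores were 0.05, -0.22 and -0.05 with DMSO and -0.05, 0.25 and 0.02 with GIA, and CA9 spanned 4.34-fold with DMSO and 3.45-fold with GIA. Treatment was the same within a group, so it cannot by itself separate libraries of that group, and overlap of the groups is no test of this. Between groups, 2 treated libraries lay inside the range of the DMSO libraries and GIA library 2 lay above it, which leaves a treatment effect open. A bias of gene length and GC content is argued against, as 95.6% of the range was left after both trends were removed. Total depth did not separate GIA libraries 1 and 2, whose totals differed by 0.00184% while their scores differed by 0.30, 64.8% of the whole range. The SE of 0.06 over 41 genes of these 2 libraries takes the genes as independent. Their estimated correlation was 0.328, so that SE is too small. Whether the gap exceeds the noise of single libraries was therefore not settled. Over all 6 libraries depth stays open, since the Spearman rho of score and total was 0.257 (exact p = 0.658, 95% interval -0.72 to 0.89). This rho is under the limit of 0.4 set beforehand and by that limit alone counted against depth. The interval, considered only once the value was known, does not exclude a strong relation. No difference between cultures was tested.

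The most variable 10% of genes overlapped another gene model on the same strand more often than the rest, 41.6% against 26.5%. Reads shared between overlapping models may add to this variation: the odds ratio was 1.97 (95% interval 1.75 to 2.21, Fisher's exact p = 6.18e-30), just under the value of 2 set beforehand, so the test did not settle it. Low counts may account for part of the pattern, since the odds ratio was 1.30 (95% interval 1.09 to 1.55) among genes with a mean FPKM of at least 5, between the limits of 1.2 and 2 set beforehand; no biological explanation was tested. RPS10 had 153, 168 and 147 FPKM with DMSO and 222, 236 and 155 with GIA, while the readthrough model RPS10-NUDT3 had 58.6, 51.1 and 60.0 and then 17.8, 18.6 and 54.6. BSCL2 had a log2 fold change of -0.44 (SE 0.12) and HNRNPUL2-BSCL2 0.59 (SE 0.16). Of the 11 genes called only with a library left out or with the replicate block, 7 overlapped another model on the same strand, against 28.0% of tested genes.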
